A study of Mus musculus with 13 samples.

How the data were processed

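Single CD8+ T cells from mouse spleen were sorted straight into a reverse transcription and preamplification mix, per the labels' protocols, amplified with pooled TaqMan assays for 18 cycles, diluted 5-fold and measured on Fluidigm dynamic arrays with a BioMark instrument, whose software gave the Ct values. Cells at days 5, 7 and 45 came from recipients of 5000 OT-1 cells, those at day 3 from recipients of 20000 and those of the first division, at day 2, from recipients of 2000000 dye-labelled cells, per the labels. The labels name staining for CD8, CD44, CD4 and markers of myeloid cells. The gates for proximal, distal, Tmp, Tsle, Tcm and Tem cells, the number of mice, the array each cell was run on, and any filter on cells are not given in the sources used here.

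The deposited file is 1 table of 95 assay rows and 1449 cells, with Il2 measured by 2 rows, and columns named by population alone. Its values are log2 amounts as deposited, on the scale of PCR cycles, and the labels call them Ct and not normalized. The values grow with the amount of RNA and hold 0 for no detection, so they are not Ct as the labels say. The design, written for Ct, was kept with this reading. The smallest value above 0 was 1.01 and the highest 35.0. They were read as 40 minus Ct, where 40 is inferred from the values, and the sign was settled by R18s and Actb, the most abundant transcripts, having the highest values. Across the 86 assays with at least 10 detected cells, the share of cells above 0 and the median value in them had a Spearman rho of 0.24. Of the 95 rows, 93 were matched by accession to the mouse RefSeq table of assembly GRCm38.p6, which was used for names only. In 3 of them the symbol replaced the name in the file (Actb, Bnip3l and Tnfrsf1b), and the 2 others, R18s and Mela, kept the name in the file. No genome build is named by the authors, so no coordinates are given.

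The level of a gene in a cell was set to 28 minus Ct, the deposited value minus 12, and to 0 below that limit or without detection. Of the values above 0, 11.9% lay at or below the limit. The mean level over all cells of a population was compared between 10 pairs of populations fixed before the data were examined. Because each population is 1 sample and cells are not replicates, no test was run, and genes were counted by size, at least 1 cycle. The text names the 12 largest positive and 12 largest negative differences of at least 1 cycle per comparison, and members of 17 gene lists, all fixed before the data were examined. Klrg1, Il7r, Cd44, Cd8a and Il2ra were among the genes taken as possible gates. Some genes counted in the totals are not reported here by name. The reference gene list had 2 measured members, Actb and Gapdh. For lists with at least 5 measured members, the median difference was ranked among 10000 random lists of the same size matched by tertile of mean level. Shares of cells in the text use the deposited detection (a value above 0) with exact 95% binomial intervals from scipy. Shares at the limit of 28 are among the alternatives. Each cell was assigned to the nearer of the mean profiles of day 7 Tsle and Tcm by Euclidean distance over the levels of all genes. Bmp2 and Serpinb6b were above 0 in 0 of 1449 cells (up to 0.207%).

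Precision is set by the number of cells, from 48 distal to 154 unsorted day 5 cells. A transcript found in no cell can have a share of up to 1.95% (154 cells) to 6.25% (48 cells). Alternatives chosen before the data were examined were detection limits of 24 and 26 and none, a minimum of 20 detected assays per cell, centring on Actb and Gapdh or on the 2 genes detected in at least 90% of cells of every population (R18s and Actb), means of detected cells, shares, medians, a gene filter of 10% of cells, another distance and other reference populations, and the earlier or later columns of each population alone. After seeing the data, 4 were added: a minimum of 10 assays, shares of values above 0, leaving out 17 assays whose median in detected cells ranged over more than 4 cycles between the earlier and later columns of all populations, and counting only genes at least 1 cycle apart in all 4 pairings of earlier and later columns. The comparison of earlier with later columns within a population was also added then.

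Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The size rule was tested on simulated data drawn from the naive cells, with 20 of 95 rows changed by 2 cycles: all 20 were called in the right direction and 0 of the unchanged ones, and 96.4% of simulated intervals held the true share. This simulation has no shift between arrays.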

Results

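Single CD8+ T cells were profiled by quantitative PCR for 94 genes as they responded to Listeria monocytogenes expressing ovalbumin in mice. Transgenic OT-1 T cells, whose receptor recognises an ovalbumin peptide, were transferred into recipients infected with 5000 colony-forming units of the bacterium. For naive, proximal and distal cells the labels give neither the number of cells transferred nor the dose. From first-division cells to days 3 and 5, the number transferred fell from 2000000 to 20000 and 5000. Differences between these populations cannot be told apart from an effect of that number. The 13 populations were naive cells, cells after the first division at day 2, the proximal and distal daughters of that division, unsorted responders at days 3, 5 and 7, sorted memory precursor (Tmp) and short-lived effector (Tsle) cells at days 5 and 7, and central (Tcm) and effector memory (Tem) cells at day 45. Each population was 1 sample of 48 to 154 cells, 1449 cells in all, and the number in each equalled the number stated by the submitters. With 1 sample per population there was no replicate, so no test was possible and no p-value is given. Genes are described by the size of their difference and by the share of cells in which they were found, followed by an exact (Clopper-Pearson) 95% interval. These intervals cover counting error only, and where no cell had the transcript, the upper limit that 3 cells would give is stated.

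The labels call the values Ct, in which more RNA gives a lower number, but the deposited values run the other way. A value of exactly 0, which stood for no detection, made up 83.4% of the table, and the 18S ribosomal RNA assay (R18s) had the highest median, 27.4, above Actb at 20.1. The values were therefore read as 40 minus Ct, an offset inferred from the values and not stated. A level here is the number of cycles above the detection limit of Ct 28 (a deposited value of 12), with undetected cells at 0, and 1 cycle corresponds to a doubling of template at full PCR efficiency. Signed differences are first population minus second, so positive means more transcript. R18s, Actb and Gapdh were above 0 in 100% of cells. The median number of assays above 0 per cell was 12 in naive cells, 12 in distal, 18 in proximal and 18 in first-division cells, 16 at day 3, 19 at day 5 and 17 at day 7. It was 16 in day 5 Tmp, 17 in day 5 Tsle, 14 in day 7 Tmp, 13 in day 7 Tsle, 17 in Tcm and 11 in Tem. Over all cells, Cd4 and Foxp3, markers of other T cells, were each above 0 in 2 of 1449 cells (0.138%, interval 0.0167 to 0.498%), and Gata3 in 53 (3.66%, 2.75 to 4.76%).

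The columns of most populations fell into consecutive stretches that differed in height for single assays. Each population's columns were therefore also split in 2 equal parts by file order, called its earlier and later columns. Between these parts of the same population, 0 to 6 genes (median 4) differed by at least 1 cycle, and 0 to 9 (median 3) differed by at least 20 percentage points in share. Lgals1 in unsorted day 5 cells had a median value of 12.2 in the earlier columns and 18.1 in the later ones, though it was above 0 in 100% and 97.4% of those cells. Counts of genes below are to be read against these numbers. For day 7 against naive, proximal against distal, and Tsle against Tmp at days 5 and 7, the genes at least 1 cycle apart were no more than this range. Their number alone does not set these comparisons apart from differences within a population.

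**Figure D1:**
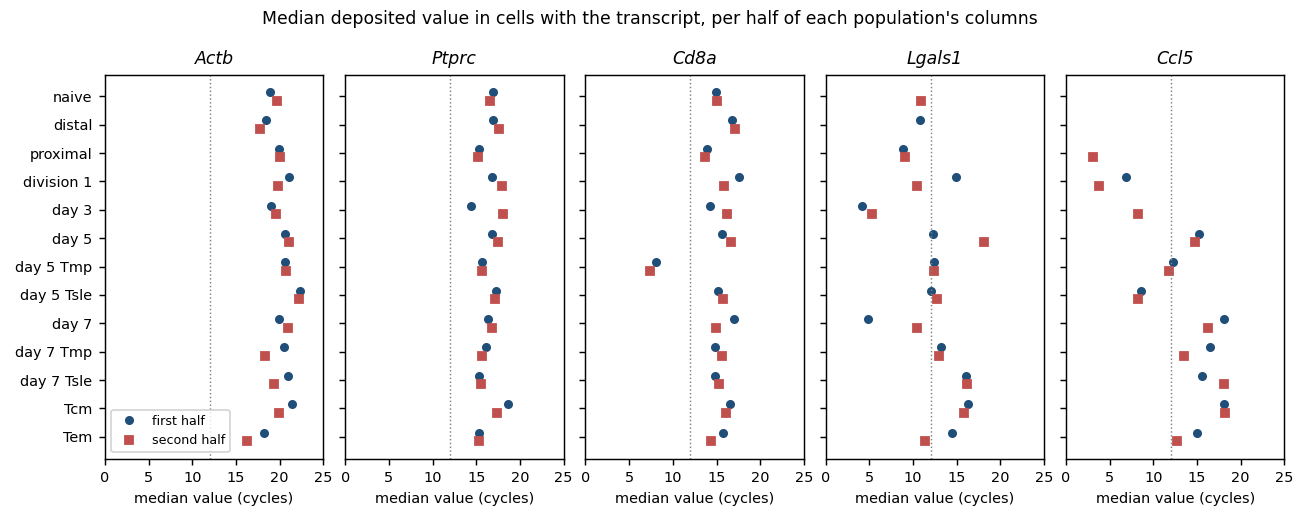
Median deposited value (horizontal axis, cycles, higher is more transcript) of 5 genes in cells with a value above 0, for the earlier (circles) and later (squares) columns of each population, where at least 3 such cells were found. The dotted line is the detection limit of 12. Actb medians stayed between 16.3 and 22.3, whereas Ccl5 sat at 8.45 over all day 5 Tsle cells with the transcript and at 14.9 over those of unsorted day 5.

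After the first division, cells carried more transcript of Myc, the growth and cell cycle regulator, and of the interleukin-2 receptor chains Il2ra and Il2rb than naive cells did. Myc was found in 54.9% of first-division cells (46.4 to 63.2%) and 10.7% of naive cells (6.26 to 16.9%), with a level difference of 2.47 cycles. Il2ra was found in 45.1% (36.8 to 53.6%) against 4.70% (1.91 to 9.44%), a difference of 1.89 cycles. The transcription factors Eomes and Irf4 were higher by 1.25 and 1.03 cycles, with Irf4 in 38.9% of first-division cells (30.9 to 47.4%) and 0 of 149 naive cells (up to 2.01%). Klf2, which maintains lymphocyte recirculation and quiescence, was lower (34.7 against 79.9% of cells, -1.89 cycles), as was the interleukin-7 receptor Il7r (6.25 against 32.9%, -1.05 cycles).

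In all, 9 of 94 genes were at least 1 cycle higher in first-division cells and 3 were lower. The other genes higher were Cd8a (1.52 cycles), Gapdh (1.51), Actb (1.14) and the proteasome subunit Psmb7 (1.02). The Actb difference ran from -0.01 to 2.30 cycles between pairings of earlier and later columns. Of the 11 effector transcription factors, 2 were higher and none lower. The 9 naive and memory factors had none higher and 1 lower, Klf2, while Tcf7 differed little in share (70.8 against 75.2%). Of 6 cytokine receptors, 2 were higher and 1 lower, and none of the 7 cytotoxic and effector genes reached 1 cycle. Centring each cell on Actb and Gapdh left 2 genes higher and 3 lower, and centring on R18s and Actb 3 and 3. Casp9 was found in 33.3% of the earlier and 1.39% of the later first-division columns.

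At day 3 Il2ra, Myc and Il2rb were still higher and Klf2 still lower than in naive cells, while Tcf7, a factor of naive and memory cells, was found as often. Il2ra was higher by 1.61 cycles (50.3% of cells, 41.9 to 58.8%), Myc by 1.56 (45.5%, 37.1 to 54.0%) and Il2rb by 1.14 (44.1 against 19.5%). Klf2 was lower (-2.06 cycles, 37.8% of cells), as were Il7r (-1.02 cycles, 9.09%) and R18s (-1.14 cycles, which ran from -2.30 to 0.03 between pairings of earlier and later columns). Tcf7 was above 0 in 76.2% of cells (68.4 to 82.9%) and 75.2% of naive cells (67.4 to 81.9%). Il2 itself was found in 11 of 143 cells (7.69%, 3.90 to 13.3%), in 0 of 149 naive cells (up to 2.01%), and in only 3 other cells of the series.

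These were 3 genes higher and 4 lower. Of the 6 cytokine receptors 2 were higher and 1 lower, of the 9 naive and memory factors 1 was lower, and none of the 11 effector transcription factors or 7 cytotoxic genes reached 1 cycle. By share, the chemokines Ccl4 and Ccl3 were found in 22.4% and 14.7% of cells, against 0.671% and 0 of 149 naive cells. The effector factors Irf8 and Irf4 were found in 29.4% and 24.5% of day 3 cells, each against 0 of 149 naive cells. In cells with the transcript, Irf4 had a median value of 5.92 in the earlier day 3 columns and 14.4 in the later ones. The former lies below the detection limit, and only 8.39% of day 3 cells had Irf4 past it, so its level hides this difference in share. Centring on Actb and Gapdh gave 3 higher and 2 lower, and on R18s and Actb 4 and 2. Ptprc, which encodes the leukocyte antigen CD45, had a median value of 14.4 in the earlier day 3 columns and 18.0 in the later ones.

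At day 5, Ccl5, Lgals1, Cxcr3 and Zeb2 were found in far more cells than in the naive population. The chemokine Ccl5 was found in 87.7% of unsorted cells (81.4 to 92.4%) and 1.34% of naive cells (0.163 to 4.76%), a difference of 2.51 cycles. Lgals1, encoding galectin-1, was found in 98.7% (95.4 to 99.8%) against 4.70% (3.41 cycles), and the chemokine receptor Cxcr3 in 68.8% (60.9 to 76.0%) against 5.37% (3.53 cycles). The level difference of Lgals1 ran from 1.08 to 5.75 cycles between pairings of earlier and later columns. Its median in unsorted cells with the transcript, 15.9, lay above those of day 5 Tmp (12.4) and Tsle (12.3). Zeb2, a transcription factor of terminal effectors, was found in 31.8% (24.6 to 39.8%) against 1.34% (1.16 cycles). Tcf7, still common at day 3, was lower, found in 13.6% (8.64 to 20.1%, -2.89 cycles). Klf2 was found in 93.5% of unsorted day 5 cells (88.4 to 96.8%), 1.14 cycles above naive. Its median in cells with the transcript was 16.8 there and 15.8 in both day 5 Tmp and Tsle, so this rise is stated for unsorted cells only.

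Altogether 10 genes were higher and 3 lower than in naive cells. Among them were also Il2rb (2.58 cycles), Actb (1.68), Il2ra (1.15) and Cd8a (1.11), and Il7r, which was lower (-1.08 cycles). Of the 7 cytotoxic and effector genes 1 was higher, and of the 11 effector transcription factors 1 was higher. The 9 naive and memory factors had 1 higher (Klf2) and 1 lower (Tcf7). Prdm1, an effector transcription factor, was found in 32 of 154 day 5 cells (20.8%) and 0 of 149 naive cells (up to 2.01%), and Gzmb, encoding granzyme B, in 37 of 154 against 11 of 149. Tbx21, encoding T-bet, was found in 1 of 154 day 5 cells (0.649%, 0.0164 to 3.56%), and in no more than 3 cells of any population, so this assay held no comparison. Centring on Actb and Gapdh left 6 higher and 3 lower, and on R18s and Actb 5 and 3.

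At day 7, Ccl5, Zeb2 and Cxcr3 were higher than in naive cells, and Myc and Il2ra were found in fewer cells than at day 3. Ccl5 was found in 96.3% of cells (91.5 to 98.8%, 4.66 cycles above naive), Zeb2 in 43.3% (34.8 to 52.1%, 1.48 cycles) and Cxcr3 in 37.3% (29.1 to 46.1%, 1.21 cycles). Klrg1, a receptor of short-lived effector cells, was found in 24.6% (17.6 to 32.8%) and 0 of 149 naive cells (up to 2.01%). Tcf7 was lower (30.6%, 22.9 to 39.1%, -1.82 cycles), although its mean level in the cells that had it was 0.65 cycles above naive. Myc was found in 2.99% of cells and Il2ra in 11.2%.

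Thus 3 genes were higher and 2 lower at day 7. Of the 11 effector transcription factors 1 was higher, and the median difference of this list, 0.25 cycles, lay at percentile 98.2 of random lists matched on level. Among the 7 cytotoxic and effector genes 1 was higher, and none of the 6 cytokine receptors reached 1 cycle. Centring on Actb and Gapdh gave 5 higher and 2 lower, and on R18s and Actb 2 and 4.

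Central memory cells at day 45 combined naive-like shares of Tcf7 and Klf2 with Ccl5 in every cell. Ccl5 was found in 100% of Tcm cells (97.4 to 100%) and differed from naive by 6.06 cycles, the largest difference of the 10 comparisons. Lgals1 (54.3% of cells, 2.25 cycles), Cxcr3 (61.6%, 2.17 cycles) and Il2rb (63.0%, 1.76 cycles) were higher, as were Actb (1.58), Cd8a (1.43), Ptprc (1.27) and Pdcd1 (1.03 cycles), the gene of the inhibitory receptor PD-1. Tcf7 was found in 71.7% of Tcm and 75.2% of naive cells, and Klf2 in 81.9% against 79.9%. Pdcd1 was found in 29.0% of the earlier and 1.45% of the later Tcm columns.

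Of the 94 genes, 8 were higher and 0 lower in Tcm than in naive cells. The 7 cytotoxic genes had 1 higher, the 6 cytokine receptors 1 and the 6 activation and inhibition genes 1. Neither the 9 naive and memory factors nor the 11 effector factors had a member 1 cycle apart, and by share the chemokine receptor Ccr7 was lower (11.6 against 34.9%). Centring on Actb and Gapdh left 6 higher and 1 lower, and on R18s and Actb 5 and 1.

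Effector memory cells shared Ccl5 with Tcm but had Tcf7 less often than naive cells. Ccl5 was found in 99.3% of Tem cells and was 1.80 cycles above naive, from 0.71 to 2.89 between pairings of earlier and later columns. Tcf7 was found in 47.8% (39.2 to 56.5%, -1.65 cycles), and Actb (-2.05), R18s (-1.94), Ptprc (-1.63) and the zinc finger gene Zfp281 (-1.14 cycles) were lower as well, so that 1 gene was higher and 6 lower. Zeb2, an effector factor, was found in 24.3% of Tem cells (17.3 to 32.4%) and 1.34% of naive cells. The median of the 7 cytotoxic genes, 0.12 cycles, lay at percentile 99.8 of random lists. Centring turned the balance to 4 higher and 1 lower with either reference.

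Against Tcm, 0 genes were higher and 12 lower in Tem. Receptors were among them: Il7r (15.4 against 52.9% of cells, -1.64 cycles), Il2rb (20.6 against 63.0%, -1.61) and Cxcr3 (23.5 against 61.6%, -1.41). Ccl5 was lower in amount (-4.25 cycles) but not in share, and Tcf7 in both (47.8 against 71.7%, -1.56). Also lower were Actb (-3.63), Ptprc (-2.90), Cd8a (-1.65), Lgals1 (-1.57), R18s (-1.53) and Pdcd1 (-1.03 cycles). In shares, Eomes was lower in Tem (5.88 against 29.0%), Zeb2 was higher (24.3 against 7.97%), and Klf2 was close (74.3 against 81.9%).

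Of the 6 cytokine receptors 2 were lower, of the 9 naive and memory factors 1, of the 7 cytotoxic genes 1 and of the 6 activation genes 1. The median difference of the cytotoxic list, 0.02 cycles, lay at percentile 99.3 of random lists. Tem cells had fewer assays above 0 (11 against 17) and less Actb, and after centring on Actb and Gapdh 2 genes were higher and 5 lower, while R18s turned to 0.79 cycles higher. With R18s and Actb as reference the numbers were 3 and 4. Il7r may have been part of the gate, which the sources used here do not give.

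**Figure D2:**
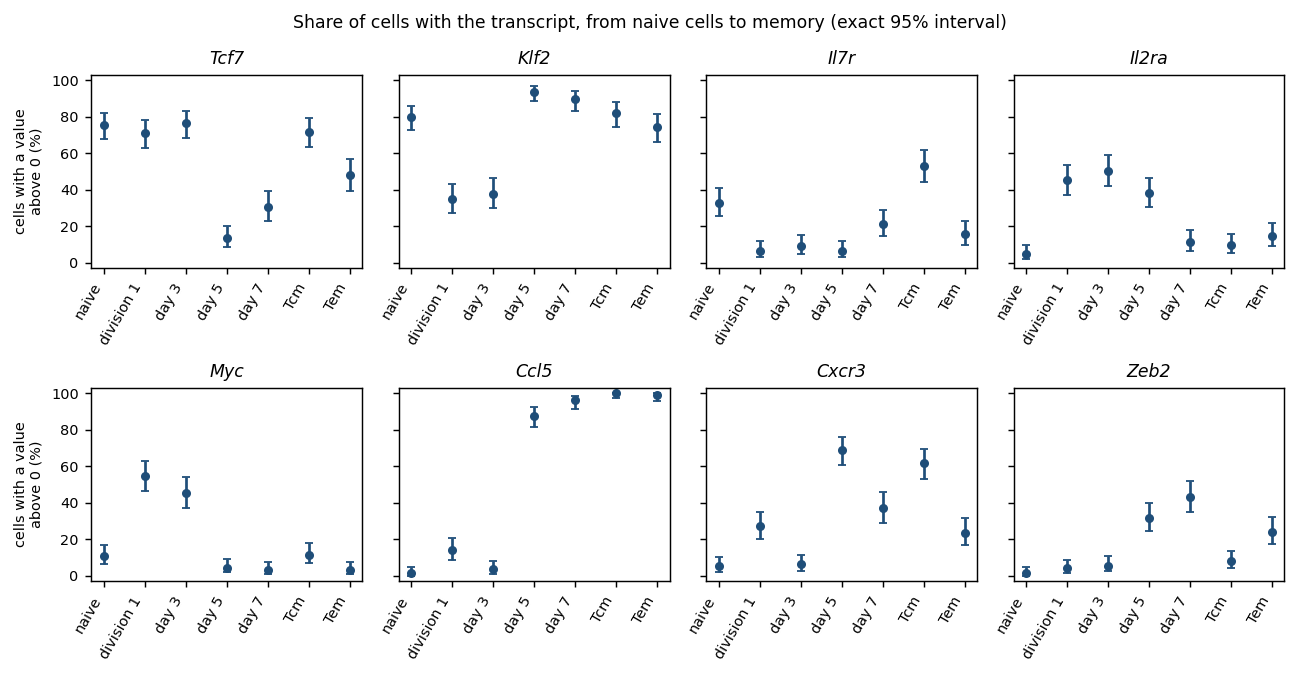
Share of cells (vertical axis, percent) with a value above 0 for 8 genes in naive, first-division, day 3, day 5, day 7, Tcm and Tem cells; points are the share in 1 sample and bars the exact 95% interval. Tcf7 was found in 75.2% of naive, 13.6% of day 5 and 71.7% of Tcm cells, and Ccl5 in 3.50% of day 3 and 87.7% of day 5 cells.

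The proximal and distal daughters of the first division were compared to ask whether the division itself yields cells with different transcripts. Proximal cells had Cxcr3 far more often (48.2%, 37.1 to 59.4%, against 4.17%, 0.509 to 14.3%), a level difference of 1.36 cycles. The receptors Ccr7 (54 of 83 against 12 of 48 cells) and Il2rb (40 of 83 against 12 of 48) were also found in more proximal cells, with level differences of 0.13 and 0.64 cycles. Cd28 was above 0 in more proximal cells (54.2 against 10.4%), but all its proximal values lay below the detection limit, so its direction turned there (0 against 8.33% of cells, -0.11 cycles). Gzmb was found in 14 of 83 proximal cells (16.9%, 9.54 to 26.7%) and 0 of 48 distal cells (up to 6.25%). Myc (61.4 against 45.8%), Il2ra (32.5 against 27.1%) and Klf2 (37.3 against 31.2%) were closer.

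By level, 3 genes were higher (Actb 1.85, Gapdh 1.41 and Cxcr3) and 2 lower (Ptprc, -1.35 cycles, among them). Ptprc was above 0 in more proximal than distal cells (98.8 against 85.4%), opposite to its level. The 11 effector factors, 9 naive and memory factors, 6 cytokine receptors and 7 cytotoxic genes had no member 1 cycle apart. Proximal cells also had more assays above 0 (18 against 12), 8 genes were at least 20 points higher in share and 0 lower, and centring gave 0 higher and 6 lower (Actb and Gapdh) or 1 and 3 (R18s and Actb). Cxcr3 also differed between the earlier and later first-division columns (11.1 and 43.1%).

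Among day 5 cells, Tsle lacked Tcf7 and carried Klrg1 more often than Tmp. Tcf7 was found in 0 of 79 Tsle cells (up to 3.80%) and 38.9% of Tmp cells (28.8 to 49.7%), a difference of -1.16 cycles. Klrg1 was found in 40.5% (29.6 to 52.1%) against 1.11% (0.0281 to 6.04%), with no difference in level (-0.00 cycles) because nearly all its values lay below the detection limit of 12, and Zeb2 in 28 of 79 cells (35.4%) against 15.6% (8.77 to 24.7%), 1.04 cycles. Cd28 (24.1 against 55.6%) and Il7r (1.27 against 16.7%) were found less often in Tsle. Klrg1 and Il7r may have been gates and are then no finding.

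By level, 5 genes were higher in Tsle (among them Cd8a 1.91, Ptprc 1.59, Actb 1.52 and Zeb2) and 1 lower. None of those named differed by 20 points in share, and Cd8a was found in 55.7 against 44.4% of cells at median values of 15.4 and 7.78, so its difference is one of height. Of the 11 effector factors 1 was higher, of the 9 naive and memory factors 1 was lower, and the cytotoxic genes and cytokine receptors had none. Centring left 0 higher and 0 lower (Actb and Gapdh) or 1 and 2 (R18s and Actb).

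Day 7 Tsle and Tmp cells differed in the same factors. Tcf7 was found in 3.37% of Tsle (0.701 to 9.54%) and 41.9% of Tmp cells (29.5 to 55.2%, -0.90 cycles), Zeb2 in 48.3% (37.6 to 59.2%) against 19.4% (10.4 to 31.4%, 0.94 cycles) and Klrg1 in 28.1% (19.1 to 38.6%) against 0 of 62 cells (up to 4.84%), although only 7.87% of Tsle cells had Klrg1 past the detection limit. Cxcr3 was lower in Tsle (24 of 89 against 39 of 62 cells, -2.47 cycles) and Lgals1 higher (85.4 against 59.7%, 2.69 cycles). The median Lgals1 value of unsorted day 7 cells, 6.38, lay far below those of Tmp (13.1) and Tsle (16.1), so its difference in height is not separated from a shift between arrays. Il7r (2.25 against 19.4%) was found less often, with the same reservation about gates.

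Here 2 genes were higher, Lgals1 and Ccl5 (1.38 cycles), and 2 lower, Cxcr3 and R18s (-1.06 cycles). Each of them is among the 17 assays whose height shifted, and without those assays 0 genes were higher and 0 lower. Their differences in level are therefore not separated from a shift between arrays. Ccl5 was found in 97.8 and 95.2% of cells, and in the earlier columns its difference was -0.53 cycles, while R18s differed by 0.83 cycles in the later ones. The 11 effector factors had no member 1 cycle apart but a median of 0.05 cycles at percentile 98.9 of random lists. Of the 7 cytotoxic genes 1 was higher, and the cytokine receptors and naive and memory factors had none. Centring gave 3 higher and 3 lower (Actb and Gapdh) or 4 and 1 (R18s and Actb).

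**Figure D3:**
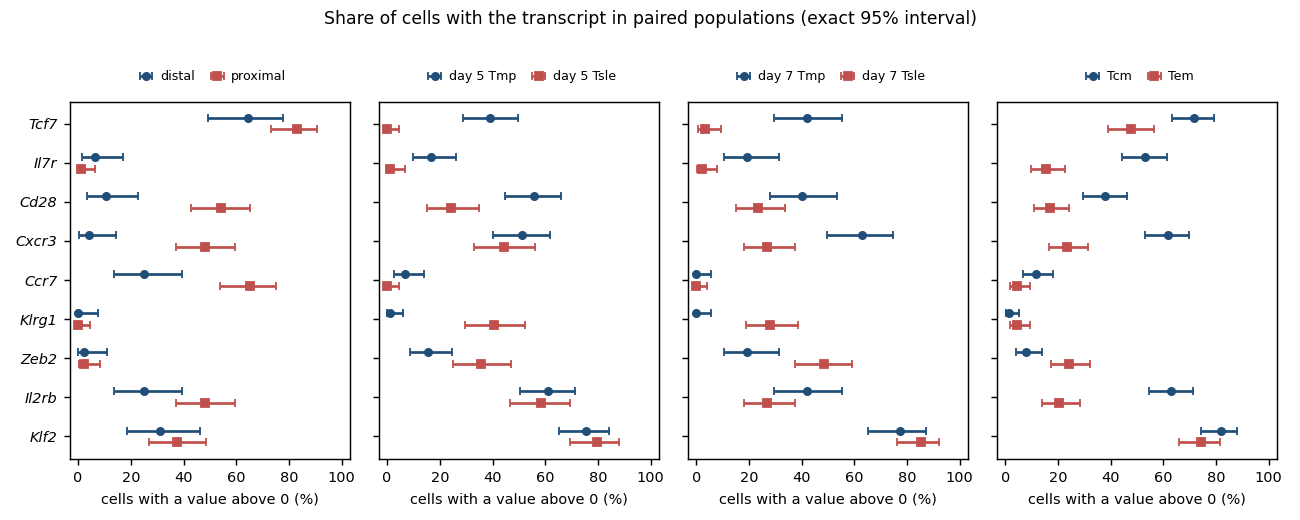
Share of cells (horizontal axis, percent) with a value above 0 for 9 genes in distal and proximal daughters, Tmp and Tsle cells at days 5 and 7, and Tcm and Tem cells; circles are the first and squares the second population of each panel, bars the exact 95% interval. Tcf7 was found in 38.9% of day 5 Tmp and 0 of 79 day 5 Tsle cells, and in 64.6% of distal and 83.1% of proximal cells.

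Whether the daughters differed along the axis of later fates was asked across genes, which are not independent replicates. Over the 94 genes, the proximal minus distal difference had a Pearson r of -0.02 and a Spearman rho of 0.01 with Tsle minus Tmp at day 5, -0.10 and -0.02 at day 7, and -0.06 and -0.01 with Tem minus Tcm. No relation was apparent, and other settings moved r at day 5 from -0.14 to 0.47.

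Single cells were also set against the mean profiles of day 7 Tsle and Tcm. Nearer to Tsle were 50.0% of distal cells (35.2 to 64.8%), 65.1% of proximal (53.8 to 75.2%), 38.9% of first-division (30.9 to 47.4%) and 61.5% of day 3 cells (53.0 to 69.5%). The shares were 77.9% at day 5 (70.5 to 84.2%), 87.8% in day 5 Tmp (79.2 to 93.7%), 96.2% in day 5 Tsle (89.3 to 99.2%), 67.9% at day 7 (59.3 to 75.7%) and 71.0% in day 7 Tmp (58.1 to 81.8%). Naive cells, which belong to neither, were nearer to Tsle in 62.2% of their earlier and 34.7% of their later columns, and Tem cells in 94.1% of each. The shares of distal, first-division and day 3 cells lie within what naive cells gave, and that of proximal cells just above it. The share moved with the detection limit, the centring and the genes used, and the order of proximal and distal turned without the assays whose height shifted (28.9 against 31.2%), without the possible gate genes (42.2 against 50.0%) and in the later columns (54.8 against 58.3%).

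The gene lists of cytokines, apoptosis, metabolism and mTOR signalling, cell polarity and Notch, chromatin regulators, signalling and markers of other cell types, with 1 to 3 measured members each, had no member 1 cycle apart in any of the 10 comparisons. Of the 3 CD8 T cell identity genes, Cd8a and Ptprc differed as given above and Thy1 reached 1 cycle in none. The cell cycle list held Myc alone. Of 60 pairs of a list and a comparison, 4 lay above the central 95% of random lists, each given above, and 0 below it. Among 60 pairs some fall outside a central 95% without any difference, so these 4 do not single out their lists. Random lists with an equal median counted as at or below, which raises the percentile of medians near 0. The chemokine list, with a median of 0 in Tem against naive, lay at percentile 95.1. The 2 Il2 rows, of the same assay, detected the transcript in the same 14 cells and in neither row in 1435, and their values differed with an SD of 1.35 cycles. Cell-to-cell spread, the SD of level over cells, had a median over all genes of 0.31 cycles in naive cells, 0.71 after the first division, 0.77 at day 3, 0.68 at day 5, 0.66 at day 7, 0.49 in Tcm and 0.32 in Tem. This median is set largely by genes found in few cells. Over genes found in at least 10% of all cells it was 0.94, 1.51, 1.15, 1.28, 1.28, 1.06 and 0.82 cycles in the same order, with first-division cells above day 3.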

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

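The explanations for Ccl5, Id2 and the Tem cells were chosen for testing only after those results were seen.

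R18s differed in opposite directions between Tsle and Tmp cells at the 2 time points, which is why it is listed here: 0.56 cycles at day 5 and -1.06 cycles at day 7. The difference between the time points was not tested, and the day 7 value was 0.83 cycles in the later columns. The second Il2 row, which the comparisons did not use, was above 0 in 11 of 143 day 3 cells and 0 of 149 naive cells. It is the same assay as the first row and was above 0 in the same cells, so it repeats that result and adds no separate evidence.

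Ccl5 lay lower in both sorted day 5 populations (medians 12.1 in Tmp and 8.45 in Tsle cells with the transcript) than in unsorted day 5 cells (14.9). A mixture of the sorted kinds should lie between them, but the unsorted median was 2.83 cycles above the higher one. Actb, 1.30 cycles higher in Tsle, argues against less RNA per cell there, but it is 1 of the 17 shifted assays. The R18s medians were close, 27.6 in Tsle and 27.7 in unsorted cells. Less RNA in Tmp was not tested: its medians were 20.6 against 20.9 in unsorted cells for Actb and 27.1 against 27.7 for R18s. A shift between arrays and a lower amount of Ccl5 in the sorted cells both stay open, because 0 populations have a labelled array and the distance of 2.83 cycles only restates the pattern.

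Id2, a factor of effector cells, was above 0 in 58.9% of day 5 Tmp cells, with every value below the detection limit of 12 (median 7.93), and in 0 of 154 unsorted day 5 cells. If Tmp cells alone carried it, and unsorted cells were Tmp and Tsle cells only, 20.6% of unsorted cells should have it. This lies above the upper limit of 1.95% that 3 cells would give, so under that assumption a subset difference alone does not explain it. The assumption is uncertain: the Tmp part of unsorted cells implied by Tcf7, Klrg1 and Cd28 was 35.1, 66.6 and 59.7%, of which the lowest was used. Unsorted cells had 3 more assays above 0 at the median than Tmp cells, against poorer detection. An assay that worked in only part of the runs fits: in 1 population, Tcm, Id2 was found in 0 of 69 earlier and 35 of 69 later columns.

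Many genes were lower in Tem than in Tcm, with unequal gaps in the median of Actb (3.86 cycles), R18s (1.60) and Gapdh (0.74). When Tcm cells were shifted down by the Actb gap, 29.7% passed the limit for Klf2, against 73.5% of Tem cells, 43.8 points more, and 34.8% (26.9 to 43.4%) for Il7r, a possible gate, against 15.4% (9.82 to 22.6%). An equal loss of RNA for all genes does not give both, since a smaller shift would leave Il7r further apart. Zeb2, not among the possible gates, was past the limit in 22.8% of Tem cells (16.0 to 30.8%). In Tcm cells it was past it in 7.97% before the shift and 2.17% after it (0.451 to 6.22%), which a loss of RNA alone does not give either. Such a loss stays open as a part of the difference. After the shift, Il2rb (31.9 against 20.6%), Tcf7 (53.6 against 47.8%) and Cxcr3 (27.5 against 21.3%) had overlapping intervals. Differences between earlier and later columns are not the whole cause, since 7 genes were lower in all 4 pairings. These pairings cannot address arrays or sorts that differed between all Tem and all Tcm cells, which stay open because no array is labelled. Without the 17 shifted assays, 5 genes were lower. A difference between the memory subsets stays open too. After centring on Actb and Gapdh, 5 genes were lower, among them Ccl5 (-2.52), Il7r (-1.31) and Il2rb (-1.16 cycles). Klf2 (1.75) and Gapdh (1.02) were higher. Actb, also lower, and Gapdh are the reference and no evidence. Ccl5 is among the 17 shifted assays and Il7r is a possible gate. Il2rb was not lower in means of detected cells. Its measured shares lay apart (20.6%, 14.1 to 28.4%, in Tem and 63.0%, 54.4 to 71.1%, in Tcm), and overlapped only after the shift by the Actb gap. Centring does not bring back transcripts lost below detection, so this count cannot separate a subset difference from a lower RNA yield.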

How the results depend on the processing

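These choices were fixed before the data were examined, and values are given where they left the range of the main value; the cause was not tested. No paired analysis was possible because each population is 1 sample. Of 1041 differences of named genes under all other settings, 1027 kept their direction and 14 turned. Among those 14, the values of Actb centred on Actb and Gapdh and of R18s centred on R18s and Actb are set by the scaling, since each gene is part of its own reference, and say nothing about the gene. Some of the 1041 values could not turn. The gene filter and the setting without the shifted assays only leave genes out, so the differences that remain equal the main ones. All named genes were chosen for a main difference of at least 1 cycle, so these numbers do not describe smaller differences. The filter of at least 20 assays per cell gave no value for the numbers of genes, correlations or nearest shares, since it left 0 naive, 0 Tem, 3 distal, 4 day 5 Tmp, 7 day 5 Tsle, 1 day 7 Tmp and 2 day 7 Tsle cells. It gave none for the spread of these populations or of unsorted day 7 cells (9 left).

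With a detection limit of Ct 24, the numbers of genes higher were first-division against naive (1), day 3 against naive (0), day 5 against naive (3), day 7 against naive (1), Tcm against naive (3), Tem against naive (0), proximal against distal (1), day 5 Tsle against Tmp (2), day 7 Tsle against Tmp (0). Lower genes numbered, for first-division against naive (0), day 3 against naive (1), day 5 against naive (0), day 7 against naive (0), Tem against naive (2), proximal against distal (1), day 5 Tsle against Tmp (0), day 7 Tsle against Tmp (1), Tem against Tcm (5). Pearson r of the daughters' difference was, with day 5 Tsle against Tmp (0.47), day 7 Tsle against Tmp (0.11), Tem against Tcm (-0.44). By rank, rho was, with day 5 Tsle against Tmp (0.25), day 7 Tsle against Tmp (0.26). Nearer to Tsle, in percent, were distal (85.4), proximal (97.6), first-division (54.2), day 3 (80.4), day 5 (61.7), day 5 Tmp (100), day 5 Tsle (67.1), day 7 (56.7). Assays per cell were naive (5), distal (6.5), first-division (8), proximal (4), day 3 (6), day 5 Tmp (4), day 5 Tsle (5), day 5 (8), day 7 Tmp (5), day 7 Tsle (5), day 7 (6), Tcm (8), Tem (3). Spread in cycles was naive (0.00), distal (0.00), first-division (0.06), proximal (0.00), day 3 (0.0019), day 5 Tmp (0.00), day 5 Tsle (0.00), day 5 (0.0067), day 7 Tmp (0.00), day 7 Tsle (0.00), day 7 (0.0042), Tcm (0.00), Tem (0.00).

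With a limit of Ct 26, the numbers of genes lower were first-division against naive (1), day 7 against naive (1), proximal against distal (1), day 5 Tsle against Tmp (0). The numbers of genes higher were day 3 against naive (0), day 5 against naive (5), day 7 against naive (1), Tcm against naive (5), Tem against naive (0), proximal against distal (1), day 5 Tsle against Tmp (2), day 7 Tsle against Tmp (1). The daughters' difference had Pearson r with day 5 Tsle against Tmp (0.086), day 7 Tsle against Tmp (0.049). Spearman rho was, with day 7 Tsle against Tmp (0.13). The percent nearer to Tsle were proximal (89.2), first-division (47.9), day 3 (74.1), day 5 Tmp (98.9). Spread in cycles was naive (0.087), distal (0.30), first-division (0.30), proximal (0.086), day 3 (0.27), day 5 Tmp (0.14), day 5 Tsle (0.083), day 5 (0.28), day 7 Tmp (0.15), day 7 Tsle (0.099), day 7 (0.28), Tcm (0.15), Tem (0.064).

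Without a limit, the numbers of genes higher were first-division against naive (39), day 3 against naive (27), day 5 against naive (30), day 7 against naive (27), Tcm against naive (19), Tem against naive (6), proximal against distal (22), day 5 Tsle against Tmp (15), day 7 Tsle against Tmp (6), Tem against Tcm (1). The numbers lower were day 5 against naive (7), day 7 against naive (9), Tcm against naive (5), Tem against naive (20), proximal against distal (4), day 5 Tsle against Tmp (9), day 7 Tsle against Tmp (13), Tem against Tcm (29). Turned in direction were the differences of Ptprc proximal against distal (0.18).

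Centred on Actb and Gapdh, the numbers of genes higher were first-division against naive (2), day 5 against naive (6), day 7 against naive (5), Tem against naive (4), proximal against distal (0), day 5 Tsle against Tmp (0), Tem against Tcm (2). Opposite in direction were the differences of Actb first-division against naive (-0.28), Actb proximal against distal (-0.081), R18s Tem against Tcm (0.79). Lower genes numbered, for day 3 against naive (2), Tcm against naive (1), Tem against naive (1), proximal against distal (6), day 5 Tsle against Tmp (0), Tem against Tcm (5). The daughters' difference had Pearson r with day 7 Tsle against Tmp (0.16), Tem against Tcm (0.23). By rank, rho was, with day 7 Tsle against Tmp (0.17), Tem against Tcm (0.12). The percent nearer to Tsle were distal (33.3), first-division (67.4), day 3 (44.1).

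Centred on R18s and Actb, the numbers of genes higher were first-division against naive (3), day 5 against naive (5), Tcm against naive (5), Tem against naive (4), proximal against distal (1), day 5 Tsle against Tmp (1), day 7 Tsle against Tmp (4), Tem against Tcm (3). The numbers lower were day 3 against naive (2), day 7 against naive (4), Tcm against naive (1), Tem against naive (1), day 5 Tsle against Tmp (2), day 7 Tsle against Tmp (1), Tem against Tcm (4). Turned in direction were the differences of R18s Tem against naive (0.057), R18s Tem against Tcm (1.05). Pearson r was, with day 5 Tsle against Tmp (-0.13), Tem against Tcm (0.17). Spearman rho was, with day 7 Tsle against Tmp (0.17). Nearer to Tsle, in percent, were distal (22.9), proximal (32.5), day 3 (27.3), day 7 (78.4).

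In means of detected cells, the numbers of genes lower were day 3 against naive (2), proximal against distal (10). The numbers of genes higher were day 5 against naive (6), day 7 against naive (6), Tcm against naive (5), Tem against naive (0), proximal against distal (1), Tem against Tcm (1). Opposite in direction were the differences of Tcf7 day 7 against naive (0.65), Il2rb Tem against Tcm (0.12), Cxcr3 Tem against Tcm (0.41).

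By shares of cells at the limit (20 points), the numbers of genes higher were day 3 against naive (7), day 7 against naive (6), Tem against naive (3), proximal against distal (5), day 5 Tsle against Tmp (2). Lower genes numbered, for proximal against distal (0), day 5 Tsle against Tmp (3). Turned in direction were the differences of Ptprc proximal against distal (12.2 points). Pearson r was, with day 7 Tsle against Tmp (-0.29), Tem against Tcm (-0.23). By rank, rho was, with Tem against Tcm (-0.14).

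By median levels, the numbers of genes higher were first-division against naive (4), day 3 against naive (1), day 5 against naive (6), day 7 Tsle against Tmp (1).

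In the earlier columns, the numbers of genes higher were first-division against naive (14), day 7 against naive (7), Tem against naive (2). The numbers lower were Tem against naive (3), day 5 Tsle against Tmp (0), day 7 Tsle against Tmp (5). Turned in direction were the differences of Ccl5 day 7 Tsle against Tmp (-0.53). Spearman rho was, with day 5 Tsle against Tmp (0.12), Tem against Tcm (0.15). Pearson r was, with Tem against Tcm (0.26). Nearer to Tsle, in percent, were proximal (75.6), day 3 (76.1), day 7 (56.7), day 7 Tmp (51.6).

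In the later columns, opposite in direction were Actb first-division against naive (-0.011), R18s day 7 Tsle against Tmp (0.83). Lower genes numbered, for day 7 against naive (4), Tcm against naive (3), proximal against distal (4). The numbers of genes higher were Tcm against naive (5), Tem against naive (0), proximal against distal (5). The daughters' difference had Pearson r with day 5 Tsle against Tmp (-0.14), day 7 Tsle against Tmp (0.018), Tem against Tcm (-0.27). By rank, rho was, with day 7 Tsle against Tmp (0.11). The percent nearer to Tsle were day 3 (52.8), day 7 Tmp (83.9).

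Without the possible gate genes, Pearson r of the daughters' difference was Tem against Tcm (-0.26). Nearer to Tsle, in percent, were proximal (42.2), day 3 (48.3), day 5 (58.4), day 5 Tmp (76.7), day 7 (55.2).

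With 1 minus Pearson r as distance, percent nearer to Tsle were distal (31.2), proximal (34.9), day 3 (39.9), day 5 Tmp (78.9).

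With Tem in place of day 7 Tsle as the profile, percent nearer to Tem were distal (81.2), proximal (86.7), first-division (56.2), day 3 (85.3), day 5 (40.3), day 5 Tsle (88.6), day 7 (44.8), day 7 Tmp (54.8).

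With at least 20 assays per cell, spread in cycles was proximal (0.63).

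The following settings were chosen after seeing the data, and again the cause was not tested.

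With at least 10 assays per cell, the numbers of genes higher were Tem against naive (3), day 7 Tsle against Tmp (1). Spearman rho was, with Tem against Tcm (0.11).

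By shares of values above 0 (20 points), the numbers of genes higher were day 3 against naive (9), day 7 against naive (10), Tem against naive (3), proximal against distal (8), day 5 Tsle against Tmp (2). The numbers lower were Tcm against naive (1), proximal against distal (0), day 5 Tsle against Tmp (3). Opposite in direction were the differences of Ptprc proximal against distal (13.4 points).

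Without the shifted assays, the numbers of genes higher were first-division against naive (5), day 5 against naive (4), day 7 against naive (1), Tcm against naive (2), Tem against naive (0), proximal against distal (1), day 5 Tsle against Tmp (1), day 7 Tsle against Tmp (0). Lower genes numbered, for Tem against naive (3), proximal against distal (1), day 7 Tsle against Tmp (0), Tem against Tcm (5). Pearson r was, with day 5 Tsle against Tmp (0.20), day 7 Tsle against Tmp (0.081), Tem against Tcm (0.23). Nearer to Tsle, in percent, were distal (31.2), proximal (28.9), first-division (27.1), day 3 (32.2), day 5 (92.2), day 5 Tmp (76.7), day 7 (78.4).

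In all 4 pairings of earlier and later columns, the numbers of genes higher were first-division against naive (5), day 5 against naive (6), Tcm against naive (5), Tem against naive (0), day 5 Tsle against Tmp (3), day 7 Tsle against Tmp (1). The numbers lower were day 3 against naive (2), Tem against naive (2), proximal against distal (1), day 5 Tsle against Tmp (0), day 7 Tsle against Tmp (1), Tem against Tcm (7).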

Other observations

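Except for Klf2 with Il2ra, which had no prediction, genes found together in single cells were tested with predictions written before the values were seen. No predicted test here was chosen after its result. Among unsorted day 7 cells, the effector receptor Klrg1 was found in 3 of 41 cells with Tcf7 (7.32%, 1.54 to 19.9%) and 30 of 93 without (32.3%, 22.9 to 42.7%), a difference of -24.9 points. More assays were above 0 in cells with Tcf7 (19 against 16), so better RNA capture would have given the opposite. Zeb2 was also less common in cells with Tcf7 (-20.2 points), and Klrg1 more common in cells with Zeb2 (11.3 points). These 2 pairs had overlapping intervals and were left open.

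In first-division cells, the activation factor Irf4 was found in 38 of 65 cells with Il2ra (58.5%, 45.6 to 70.6%) and 18 of 79 without (22.8%, 14.1 to 33.6%), a difference of 35.7 points. Better RNA capture in cells with Il2ra stays open, since 1 of 20 other genes of similar share, Myc, differed at least as much (37.4 points) and 21 against 15 assays were above 0, although the median difference of the 20 genes was 7.36 points. Klf2, for which no prediction was written, went the other way (21.5 against 45.6%, -24.0 points) and had the lowest difference of the 20 genes.

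Between earlier and later first-division columns, 9 genes differed by at least 20 points in share. Among them, the chemokine Xcl1 was found in 29.2 and 6.94% of cells, Cd69 in 26.4 and 5.56%, Ccr7 in 44.4 and 9.72%, Tcf7 in 59.7 and 81.9%, and the ribosomal protein gene Rpl35 in 0 and 38.9%. Tox was found in 37.1% of day 3 cells and 4.55% of day 5 cells.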
